A study of Mus musculus with 14 samples.

How the data were processed

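Splenic germinal centre B cells were sorted from individual immunised mice as B220+CD95+PNA+, after enrichment of B cells, per the labels' protocols. The mice were 8 to 12 weeks old on a C57BL/6x129Sv background. Per the same protocols, 25 ng of total RNA was amplified with the NuGEN Ovation system and 3.75 ug of amplified cDNA was labelled with biotin for the Affymetrix Mouse Genome 430 2.0 array. The deposited values are log2 intensities, 1 per probe set and array, for 45101 probe sets. The submitters' processing notes name RMA, which subtracts background, normalises by quantiles and summarises the probes of a set, with its version not given in the sources used here. Quantile normalisation forces arrays to a common distribution, so a change of most genes in one direction would not be seen, and RMA compresses changes of dim probe sets.

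Of the 45101 probe sets 64 are controls. The platform annotation given with the values named 1 gene for 34945 probe sets and several for 932, and 9211 probe sets were unnamed here. Symbols were checked through the gene identifier against RefSeq for GRCm38.p6, where 34741 probe sets matched and 0 symbols changed. The named probe sets covered 18193 genes, of which 9010 had several probe sets. Each gene was represented by the probe set with the highest mean over the 14 arrays. Genes were tested if that mean exceeded the median of the non-control probe sets, 6.43, which left 10225. Of the 249 genes called in KO against WT, 97 had another probe set above that level, of which 3 had the opposite sign and 0 of these reached an unadjusted p under 0.05. No detection calls were used here.

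Groups and sex were taken from the labels. Each comparison was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) over all 14 arrays with group and sex as terms, and p-values were adjusted by Benjamini-Hochberg over the genes tested, with a threshold of 0.05. The trend replaced group by the number of floxed alleles. The 37 gene lists (693 genes, 65 of them without a named single-gene probe set) were written before the data were examined, and those with at least 5 tested genes, 32 lists, were tested with camera at a preset correlation of 0.01. Camera compares a list with all other genes. Its version with an estimated correlation and limma's fry, which tests whether the genes of a list move on balance one way, were run beside it. Lists share members, so their results are not independent. Genes were named by a rule fixed before the data were examined. It took the 10 higher and 10 lower genes with the largest change among those passing, or the 3 with the smallest p where fewer than 3 passed, up to 4 members with the smallest p per list, the 5 rising and 5 falling trend genes with the smallest p, and Crebbp and Ep300. Ptgr1, Thyn1, Ptpn9 and Clec16a enter through the trend and HET parts of the rule.

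The fits were tested on simulated data with the residual SD of each real gene, independent noise and 200 genes changed by known amounts, HET by 0.5 of the KO change. For KO against WT, 66% of genes changed by 0.5 log2 units and 96% of those changed by 1 were called, with 9 false calls among 180. For HET against WT, 12% and 65% of the same genes were called, with 3 false calls among 80. A simulated HET position of 0.5 was estimated as 0.51. A shift of -0.3 put into the 11 tested MHC class II genes was called by camera and 0 other lists were. With noise independent between genes, this does not show how often camera calls lists of correlated genes by chance. The settings tried as alternatives were the expression filter, the handling of several probe sets, repeated quantile normalisation and median centring, the sex covariate, females alone, limma's trend and robust options, array weights, fits with only the groups compared, the replicate number as a block, looser thresholds, and leaving out each array in turn. Leaving out KO 3 and WT 4 together, or the chromosome of Crebbp, and splitting the KO arrays were added after the data were seen. No pair of arrays shared more than 58 identical values, so none was a copy of another.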

Results

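Gene expression was measured in germinal centre B cells from the spleens of 14 mice, 1 Affymetrix Mouse Genome 430 2.0 array per mouse. The germinal centre is the structure in which activated B cells divide, mutate their antibody genes and are selected. Every mouse carried the Cg1-Cre transgene, which recombines floxed DNA in B cells that have been activated. The mice differed in the number of floxed alleles of Crebbp, the gene of the CREB-binding protein, a lysine acetyltransferase and transcriptional coactivator. Wild-type mice (WT) had 0 floxed alleles (n = 4, 1 of them male), heterozygous mice (HET) had 1 (n = 5, 2 males) and knockout mice (KO) had 2 (n = 5, 3 males). They were immunised with sheep red blood cells on days 0 and 5 and killed on day 12. Cells were sorted as B220+CD95+PNA+. The number of arrays limits the precision. On the tested genes the array of KO 3 had the lowest median correlation with the other arrays, 0.979, against 0.984 to 0.990 for the other 13, while over all probe sets HET 3 had the lowest, 0.984, against 0.989 to 0.994. KO 3 lay apart on the first 2 principal components, while WT 4, the only male WT mouse, lay apart on the third. The study asks whether loss of 1 or both copies of Crebbp, a gene often mutated in lymphomas of germinal centre origin, changes transcription in these cells. Named genes carry the limma log2 change with its standard error (SE), sex held as a covariate, and the Benjamini-Hochberg adjusted p over 10225 tested genes.

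Crebbp itself was lower in KO mice on all 4 of its probe sets. On the probe set with the largest difference the mean went from 10.29 ± 0.08 (SD, n = 4) in WT through 9.95 ± 0.17 (SD, n = 5) in HET to 9.42 ± 0.10 (SD, n = 5) in KO. The KO change was -0.86 (SE 0.10), 55.0% of the WT intensity, with limma adjusted p = 1.71e-06 over the 4 probe sets. On the other 3 probe sets the KO changes were -0.47, -0.41 and -0.30, with adjusted p of 0.00093, 0.00131 and 0.0396. The probe set at -0.41 is the brightest and stood for Crebbp among all tested genes. Its limma call there was narrow and was lost without the sex covariate (adjusted p = 0.0524). It was also lost without WT 1, WT 2 or WT 3 (adjusted p from 0.0845 to 0.0927). In HET only the probe set with the largest difference passed, at -0.34 (SE 0.09, adjusted p = 0.0110), which is 79.1% of WT. Where the probe sets lie relative to the deleted part of the gene was not analysed here, so the values need not measure the share of recombined cells. Ep300, the paralogue of Crebbp, differed by -0.01 (SE 0.13, limma adjusted p = 0.991) between KO and WT. Xist and Eif2s3y matched the labelled sex of every mouse.

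**Figure D1:**
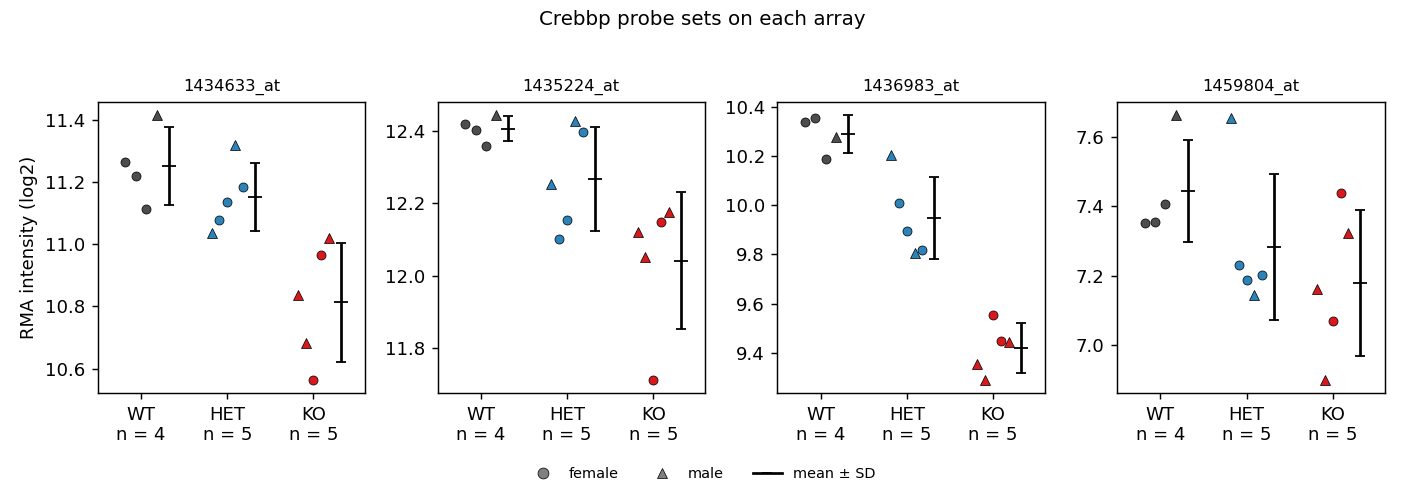
Log2 RMA intensity (y axis) of the 4 Crebbp probe sets in WT, HET and KO mice (x axis), 1 point per array, circles for females and triangles for males, with the group mean and SD. On the third probe set from the left the group means are 10.29, 9.95 and 9.42, and every KO array lies below every WT and HET array.

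Germinal centre B cells of KO mice, compared with WT cells, had higher expression of single genes of varied function, such as Fmn2, Spry2, Kdm5b and Gfi1, and lower expression of others, such as Ifnlr1, Nr4a1 and Ebi3. The genes that rose most were Fmn2, encoding a formin that nucleates actin filaments, at 2.05 (SE 0.20, 4.13-fold, adjusted p = 0.000345), and Tlcd5 at 2.01 (SE 0.21, 4.03-fold, adjusted p = 0.00035). Lowered genes included Nr4a1, a nuclear receptor induced by antigen receptor signals, at -0.86 (SE 0.10, adjusted p = 0.000848), and Ebi3, a cytokine subunit induced through CD40, at -0.61 (SE 0.09, adjusted p = 0.00419). Of the 10225 genes, 249 passed an adjusted p of 0.05 in limma, 120 higher and the others lower in KO. Changes were mostly modest, with a median size of 0.56 among the called genes. At least 2-fold differences were seen for 18 of the higher and 7 of the lower genes.

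Among the higher genes, Adgrl2, an adhesion receptor of the latrophilin family, changed by 1.53 (SE 0.25, adjusted p = 0.00569). Spry2, an inhibitor of receptor tyrosine kinase signalling, rose by 1.38 (SE 0.20, adjusted p = 0.00346), and Kdm5b, a histone H3 lysine demethylase, by 1.26 (SE 0.15, adjusted p = 0.000848). Eno2, a glycolytic enolase, and Slc25a24, a mitochondrial carrier of adenine nucleotides, each rose by 1.25. Gfi1, a zinc finger repressor of haematopoietic cells, rose by 1.23 (SE 0.15, adjusted p = 0.000934), Armcx4 by 1.22 and the phosphatase gene Ppm1e was 2.30-fold higher (adjusted p = 0.000848). The smallest p-values belonged to Ptgr1, a reductase of prostaglandins and leukotrienes, at 0.81 (SE 0.08), Thyn1 at 1.02 (SE 0.10) and the tyrosine phosphatase gene Ptpn9 at 0.87 (SE 0.08), each with adjusted p = 0.000319. Clec16a, which takes part in autophagy and mitophagy, was 2.30-fold higher (log2 SE 0.13, adjusted p = 0.000605).

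The lower genes were led by Crisp3, a cysteine-rich secretory protein, at -1.47 (SE 0.29, adjusted p = 0.0175, called in 12 of the 14 fits that left out 1 array). Pde2a, a cyclic nucleotide phosphodiesterase, changed by -1.22 (SE 0.30) and passed narrowly at adjusted p = 0.0496, in only 1 of the 14 fits that left out 1 array. Ccdc175, Tktl1, a relative of transketolase, and Tmem51 changed by -1.21, -1.19 and -1.18, with adjusted p from 0.00263 to 0.00851. Rnf183, a ubiquitin ligase, fell by 1.03 (SE 0.17, adjusted p = 0.00594) and Ifnlr1, the ligand-binding chain of the interferon lambda receptor, by 1.02 (SE 0.11, adjusted p = 0.000582). Hs3st1, a heparan sulphate sulphotransferase, Cyp27a1, a sterol hydroxylase, and Ffar2, a receptor for short-chain fatty acids, changed by -0.99, -0.96 and -0.96, with Hs3st1 called in 14, Cyp27a1 in 9 and Ffar2 in 13 of those fits. Call counts depended on single WT mice, with 130 to 161 genes when any 1 of the 4 WT arrays was left out, and 79 genes when females alone were compared. In every fit that left out 1 of the 14 arrays, 88 of the 249 genes remained called, 56 higher and 32 lower, among them Fmn2, Tlcd5, Spry2, Kdm5b, Gfi1, Ptgr1, Ifnlr1, Nr4a1 and Ebi3.

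**Figure D2:**
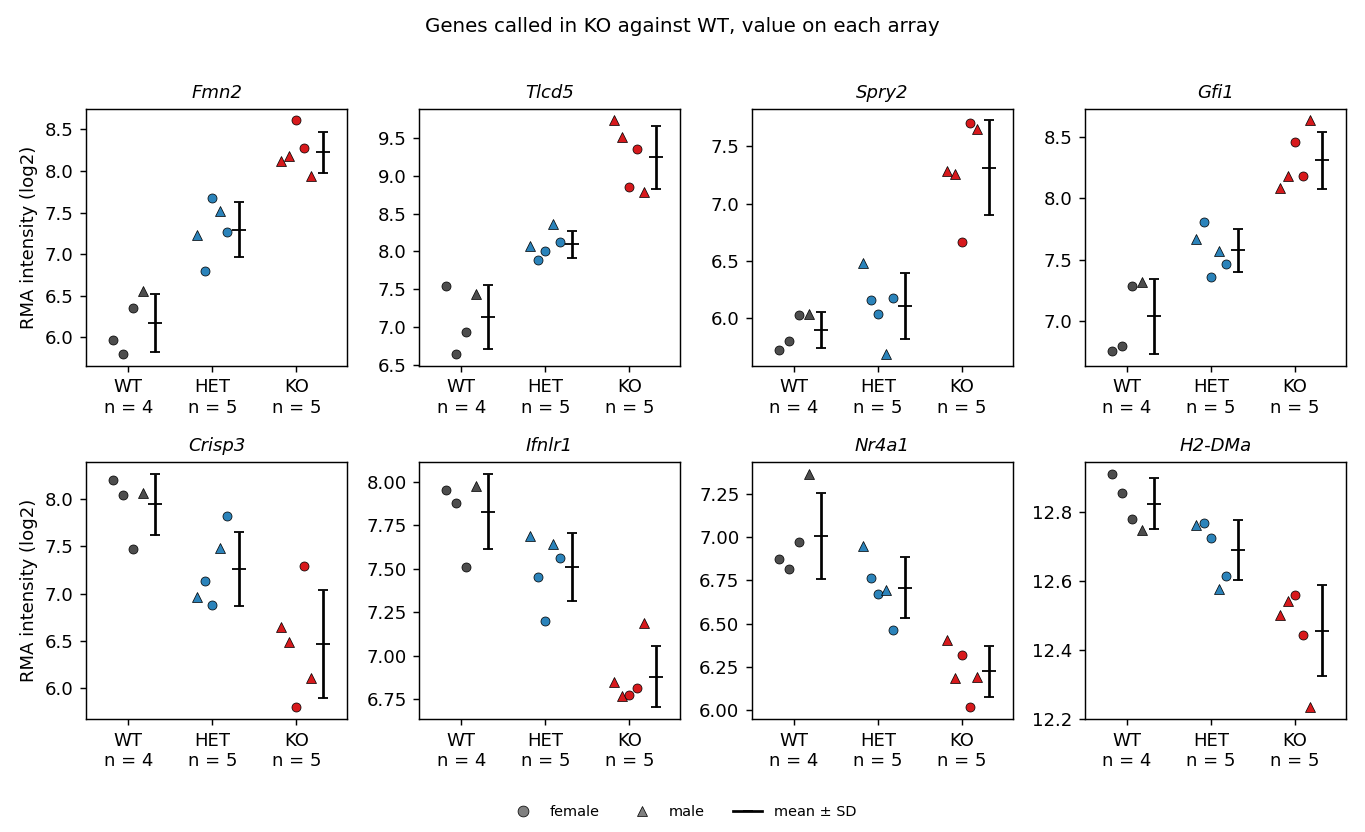
Log2 RMA intensity (y axis) of 8 genes called in KO against WT (x axis: WT, HET and KO), 1 point per array, circles for females and triangles for males, with the group mean and SD. Fmn2 has group means of 6.17, 7.30 and 8.22, and for Fmn2, Tlcd5, Gfi1 and Nr4a1 the HET mean lies between those of WT and KO.

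In KO cells the genes of the light zone, where B cells are selected with T cell help, were lower as a list in camera, though not with an estimated correlation. Of 22 tested light zone genes 20 had a negative change, with a median of -0.29. Nr4a1, the transcription factor gene Egr3 (-0.64, SE 0.14, adjusted p = 0.0271) and the activation marker Cd69 (-0.52, SE 0.13, adjusted p = 0.0496) passed over all genes, and 8 genes passed when adjusted over the list alone. Of the 14 fits that left out 1 array, Nr4a1 was called in 14, Egr3 in 9 and Cd69 in 2. Slamf1 at -0.30 (SE 0.08, adjusted p = 0.0628) and Irf4 at -0.30 (SE 0.08, adjusted p = 0.0842) did not pass over all genes. Targets of CD40 and NF-kB, which shares members with the light zone list, had 18 of 21 negative changes and a median of -0.30. There Ebi3 and the kinase gene Map3k8 (-0.67, SE 0.15, adjusted p = 0.0311, called in 9 of the 14 fits) passed, and 9 genes passed when adjusted over the list alone. Nfkb2 changed by -0.35 (SE 0.10, adjusted p = 0.102). Limma's camera with its preset correlation gave adjusted p = 8.47e-08 for the light zone and 2.25e-07 for CD40 and NF-kB, but both had an adjusted p = 0.156 with an estimated correlation. Fry gave adjusted p = 0.00858 for the light zone and 0.0119 for CD40 and NF-kB. The list of immediate early genes, which handling of cells also induces, had a camera adjusted p = 0.00828, with adjusted p = 0.312 with an estimated correlation and no member called. It was not called by fry (adjusted p = 0.0918), without KO 3 (adjusted p = 0.228) or without KO 3 and WT 4 (adjusted p = 0.103).

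Genes of antigen presentation by MHC class II were lower in KO cells as a list in camera. All 11 tested genes had negative changes, with a median of -0.22. H2-DMa, which loads peptides onto class II molecules, changed by -0.35 (SE 0.08, adjusted p = 0.0331), and the class II chains H2-Eb1 by -0.24 (SE 0.06, adjusted p = 0.0488) and H2-Ab1 by -0.22 (SE 0.05, adjusted p = 0.0489). These calls were narrow, since with 1 array left out H2-DMa was called in 8 of 14 fits and H2-Eb1 and H2-Ab1 in 1 each. H2-Oa at -0.52 (SE 0.14, adjusted p = 0.0771) did not pass, nor did Ciita, the class II transactivator, at -0.34 (SE 0.10, adjusted p = 0.121), which is named after its values were seen. Adjusted over the list alone, 7 genes passed. Camera gave adjusted p = 2.76e-07, and adjusted p = 0.156 with an estimated correlation, while fry gave adjusted p = 0.00146. In the mean of this list every KO array lay below every WT array, and the same held for light zone genes, B cell receptor signalling, dendritic cell markers, MHC class I, CD40 and NF-kB, and migration. For the first 4 of these 7 lists an exact two-sided permutation of the 9 arrays, chosen after seeing the data and without sex as a covariate, gave p = 0.00794, the smallest its 126 splits allow, and adjusted p = 0.0635 over 32 lists.

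Further lists were lower in KO cells in camera, which called 8 of the 32 lists, all lower, while 21 of 100 splits of the same arrays gave at least as many. B cell receptor signalling had 18 of 20 negative changes with a median of -0.15 (camera adjusted p = 6.69e-05, adjusted p = 0.156 with an estimated correlation) and no called member. Its smallest p-values were those of Cd79a, a signalling chain of the receptor, at -0.18 (SE 0.06, adjusted p = 0.144) and Cd22, an inhibitory coreceptor, at -0.19 (SE 0.07, adjusted p = 0.216). MHC class I presentation had 11 of 12 negative changes (camera adjusted p = 0.000672, adjusted p = 0.156 with an estimated correlation). H2-K1 at -0.24 (SE 0.07, adjusted p = 0.0821) and Tap2 at -0.27 (adjusted p = 0.167) were among the 3 genes that passed over the list alone. Targets of cAMP and CREB, the transcription factor that CREBBP was named for, had 15 of 18 negative changes (camera adjusted p = 0.000146, adjusted p = 0.156 with an estimated correlation). In this list Nr4a1, the clock gene Per1 (-0.52, SE 0.10, adjusted p = 0.0184) and Rgs2, a regulator of G protein signalling (-0.38, SE 0.09, adjusted p = 0.0424), were called, in 14, 13 and 3 of the 14 fits that left out 1 array. Migration and trafficking genes had 14 of 20 negative changes (camera adjusted p = 0.00518, adjusted p = 0.207 with an estimated correlation, and adjusted p = 0.0979 without KO 4). Rgs13, a regulator of chemokine receptor signalling in germinal centre B cells, was called there at -0.62 (SE 0.12, adjusted p = 0.018, 12 of the 14 fits), beside Rgs2 and Cd69.

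**Figure D3:**
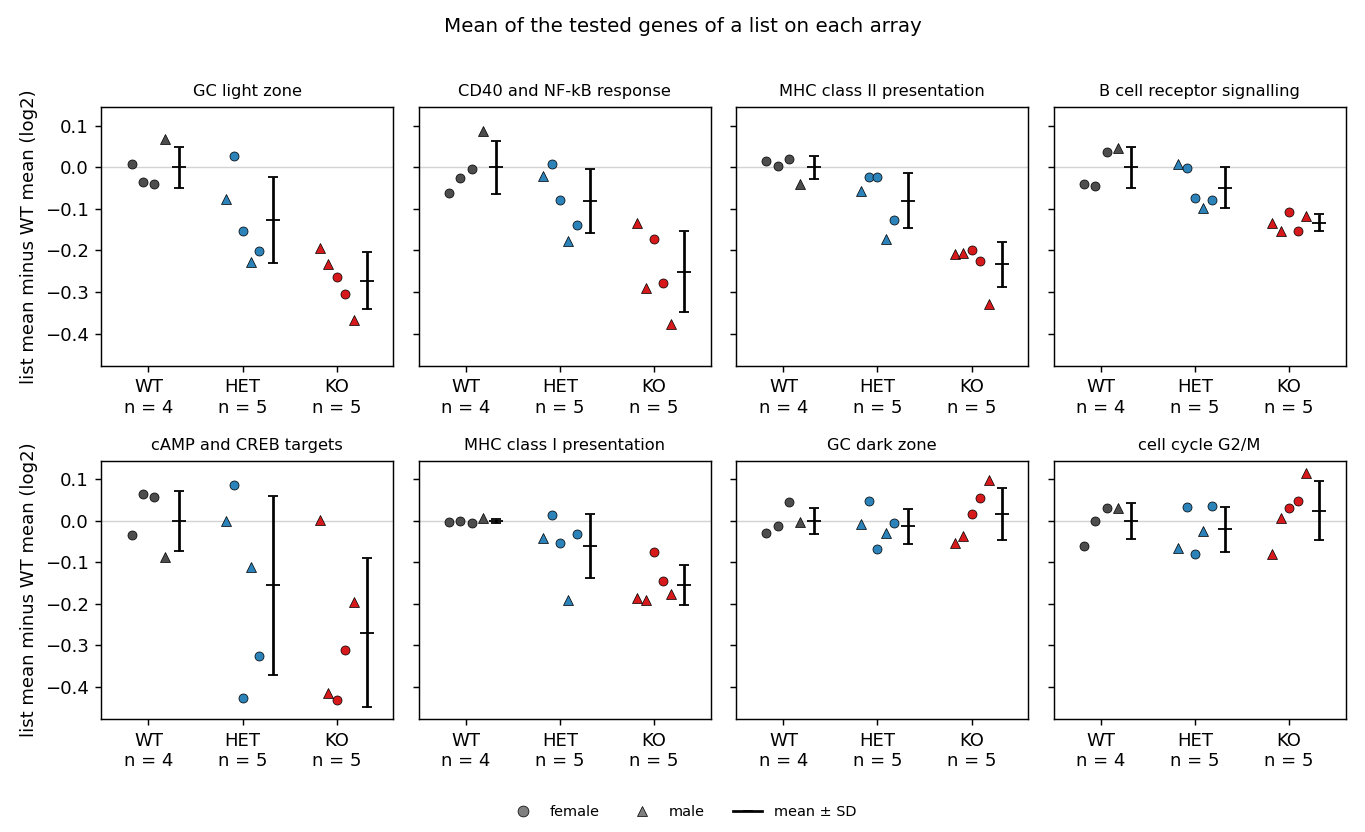
Mean log2 intensity of the tested genes of 8 fixed lists on each array, as the difference from the WT mean (y axis), in WT, HET and KO mice (x axis), circles for females and triangles for males, with the group mean and SD. In KO the MHC class II list averages -0.23 and the light zone list -0.27, and the means of the dark zone and G2/M lists are 0.02 each.

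Several programmes of germinal centre B cells did not pass the camera test in KO against WT. The dark zone list, genes of dividing and mutating cells, had 10 positive and 7 negative changes with a median of 0.03 (camera adjusted p = 0.359). Bcl6, the repressor that defines germinal centre B cells, differed by 0.00 (SE 0.05, adjusted p = 0.994), a value chosen after it was seen. The germinal centre identity list had a camera adjusted p = 0.144 with Rgs13 its only called gene. Targets repressed by BCL6 had a camera adjusted p = 0.0886, with Cd69 called, and Irf4, Cxcr5 at -0.36 and the cell cycle inhibitor gene Cdkn1b at 0.27 passing over the list alone. The plasma cell list had a camera adjusted p = 0.263. Its members differed in sign, since the surface proteoglycan gene Sdc1 rose by 0.81 (SE 0.19, adjusted p = 0.0404, called in 6 of the 14 fits), while Irf4 had a negative value. Of the p53 targets (camera adjusted p = 0.797) Zmat3 rose by 0.44 (SE 0.09, adjusted p = 0.0254, 10 of the 14 fits), and of the apoptosis regulators (camera adjusted p = 0.342) the BH3-only gene Bmf fell by 0.50 (SE 0.11, adjusted p = 0.0254, 9 of the 14 fits). Camera adjusted p was 0.797 for interferon response, 0.797 for G1/S, 0.217 for G2/M, 0.455 for DNA repair, 0.342 for MYC targets and 0.359 for oxidative phosphorylation. It was 0.30 for glycolysis, 0.062 for the unfolded protein response and 0.768 for ribosomal proteins.

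Cells with 1 floxed allele, compared with WT cells, had values between WT and KO for nearly all genes that KO changed, but no single gene passed the test on its own. The smallest p-values among higher genes belonged to Clec16a at 0.78 (SE 0.13), Ptgr1 at 0.43 (SE 0.07) and Fmn2 at 1.12 (SE 0.20), each with limma adjusted p = 0.214. Among lower genes they belonged to Gstp3, a glutathione transferase, at -0.26 (SE 0.06, adjusted p = 0.853), Myo1f, a myosin of immune cells, at -0.38 (SE 0.10) and Rnf183 at -0.57 (SE 0.16). Other values were 0.91 (SE 0.20) for Tlcd5, 0.52 (SE 0.15) for Gfi1, 0.52 (SE 0.18) for Sdc1, -0.33 (SE 0.10) for Nr4a1, -0.43 (SE 0.14) for Map3k8 and -0.12 (SE 0.07) for H2-DMa. Limma called 0 genes, with 280 at an unadjusted p under 0.05, where 511 would be found by chance among independent genes, and 6 genes were called with array weights. In simulated data with noise independent between genes, and HET changes 0.5 of those in KO, the same fit called 12% of genes changed by 0.5 in KO and 65% of those changed by 1.

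Genes of the light zone, of MHC class II presentation and of CD40 and NF-kB were lower in HET cells as lists in camera, which called 11 of 32 lists, all lower. The called lists included the light zone (18 of 22 changes negative, median -0.12, adjusted p = 0.00011), MHC class II (10 of 11 negative, median -0.06, adjusted p = 0.00327), CD40 and NF-kB (16 of 21 negative, median -0.08, adjusted p = 0.00407) and the immediate early genes (15 of 16 negative, adjusted p = 0.00327). With an estimated correlation their adjusted p were 0.238, 0.238, 0.416 and 0.238. The others were B cell receptor signalling, MHC class I, migration, cAMP and CREB targets, BCL6 repressed targets, the unfolded protein response and marginal zone markers, with camera adjusted p from 0.00407 to 0.0495, and adjusted p from 0.238 to 0.579 with an estimated correlation. With an estimated correlation, or with limma's fry, 0 lists were called, and without HET 5 camera called 3. The exact permutation of arrays, without sex as a covariate, gave a smallest adjusted p = 0.67 over the 32 lists. Its unadjusted p was 0.0635 for MHC class II, 0.0714 for the light zone and 0.151 for CD40 and NF-kB. Unchanged HET arrays, simulated after the values were seen, gave at most 8 called lists in 100 simulations. Splits of the real HET and WT arrays reached more, up to 12 lists, and 3 of 100 splits, the real one included, gave at least 11. All 8 lists called in KO had the same direction in HET, but with the shared WT arrays this was so for all lists called in KO in 15 of the 100 simulations.

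The position of HET cells between WT and KO was measured on genes called in KO against WT. Of the 249 genes, 248 (99.6%) had a HET change in the direction of the KO change and smaller than it, but these genes were chosen with the WT arrays that HET is compared with. Simulated unchanged HET arrays gave a mean of 68.5% and at most 87.5% in 100 simulations, which were chosen after the values were seen. These simulations called a mean of 648 genes in KO against WT, from 184 to 2620, and 93 of them at least 249. Their percentages therefore come mostly from larger gene sets than the real one, which limits the comparison. The exception was Prss55, a serine protease gene, with 0.04 (SE 0.08) in HET and -0.55 (SE 0.08) in KO. An unadjusted p under 0.05 for the HET change in the same direction was found for 52.2% of the genes, against a mean of 10.1% and at most 46.8% in the simulations. Adjusted over these genes alone 19.7% passed, against a mean of 0.958% and at most 29.8%, and 2 of the 100 simulations reached as much. Because both comparisons use the same WT arrays, genes were called with 2 WT arrays and both changes measured against the other 2. The sign was then the same for 92.1% of the genes, and the slope of HET on KO changes was 0.40 ± 0.03 (SD over 5 HET mice), from 0.35 to 0.44. The 5 slopes share the WT and KO arrays and the called genes, so this SD leaves out the error of those arrays. Unchanged HET arrays simulated in the same way gave a mean slope of 0.06, from -0.04 to 0.19 in 16 simulations. Like the simulations above, these took the estimated KO changes as true, so their gene sets may differ from the real ones, which limits this comparison too. Slc25a24 at 0.02 (SE 0.19) and Spry2 at 0.20 (SE 0.20) had small HET values beside KO changes of 1.25 and 1.38. Over all tested genes the covariance of HET and KO changes was 0.0162, against a mean of 0.0111 in 100 simulations without effects, where it ranged from -0.0028 to 0.0327. The correlation across genes was 0.75 with shared controls and 0.37 with split controls. In the simulations it had a mean of 0.53 and ranged from -0.24 to 0.87, so the observed value lies within that range.

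**Figure D4:**
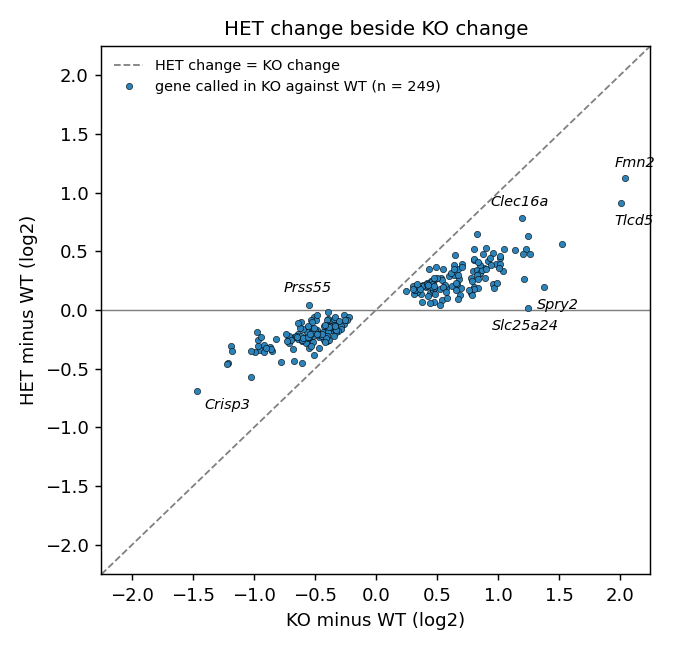
Log2 change in HET minus WT (y axis) against KO minus WT (x axis) for the 249 genes called in KO against WT, 1 point per gene, with a dashed line where both would be equal. The points lie between the line and 0, except for Prss55, at 0.04 in HET and -0.55 in KO.

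Fewer genes separated KO from HET cells. KO cells had higher Slc25a24 (1.23, SE 0.18, adjusted p = 0.0291), Spry2 (1.18, SE 0.19, adjusted p = 0.0291) and Tlcd5 (1.10, SE 0.19, adjusted p = 0.0453). They had lower Tmem51 (-0.83, SE 0.15, adjusted p = 0.0459), Hemgn, a nuclear protein of haematopoietic cells (-0.72, SE 0.12, adjusted p = 0.0453), and Ifnlr1 (-0.67, SE 0.10, adjusted p = 0.0291). Limma called 27 genes, 16 higher and 11 lower. Others higher were Armcx4, Kdm5b, the LIM domain gene Pdlim1, Ppm1e, the lipid phosphatase gene Pip4p2, Ggh, a hydrolase of folate polyglutamates, and Poglut2, a protein glucosyltransferase, from 0.96 for Armcx4 to 0.63 for Poglut2. Others lower were the RNA helicase gene Ddx25 (-0.61), Prss55 (-0.59), Nr4a1 (-0.53), Ebi3 (-0.51), Btnl2, a butyrophilin-like regulator of T cells (-0.47), the presenilin gene Psen2 (-0.44) and Aldh3b1 (-0.31). All 27 genes were also called in KO against WT in the same direction, but both comparisons use the same KO arrays, so this is not independent evidence. None of the 27 stayed called in every fit that left out 1 array, and without HET 1 or without HET 5 limma called 0.

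Of the lists, camera called 6 lower and 1 higher in KO than in HET. In the exact permutation of arrays, without sex as a covariate, the smallest adjusted p over the 32 lists was 0.127. MHC class II had all 11 changes negative with a median of -0.15 (adjusted p = 1.48e-06), led by H2-Ab1 at -0.16 (SE 0.05, adjusted p = 0.395) and H2-DMa at -0.22 (SE 0.07, adjusted p = 0.407). It was the only list of the 32 that fry also called (fry adjusted p = 0.0198), with adjusted p = 0.243 with an estimated correlation. The light zone (19 of 22 negative, adjusted p = 2.61e-06) and CD40 and NF-kB (19 of 21 negative, adjusted p = 7.88e-07) were lower as well, with adjusted p = 0.28 for each with an estimated correlation. The same estimated value held for B cell receptor signalling and for cAMP and CREB targets, and for MHC class I it was adjusted p = 0.307. With 1 array left out, MHC class I was not called without HET 1 or without KO 4 (highest adjusted p = 0.0709), nor cAMP and CREB targets without KO 3 (adjusted p = 0.0803). The G2/M list was higher with 25 of 30 positive changes and a median of 0.05 (adjusted p = 0.00317, adjusted p = 0.558 with an estimated correlation, and adjusted p = 0.131 without KO 5). The difference between males and females in the KO against HET change passed for 0 genes in limma, with 234 at an unadjusted p under 0.05.

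A linear trend over 0, 1 and 2 floxed alleles was found for 311 genes in limma, 145 rising and 166 falling, and 246 of them were also called in KO against WT. The slope rests largely on the WT and KO arrays, so this overlap is not independent evidence. A gene with equal HET and WT values can pass too, since departure from a straight line was not tested. The rising genes with the smallest p were Ptgr1 (0.40 per allele), Thyn1 (0.51), Fmn2 (1.02), Ptpn9 (0.44) and Dab2ip, a Ras GTPase-activating protein (0.40), each with adjusted p = 0.000139. The falling genes were Ifnlr1 (-0.52, adjusted p = 0.00051), Nr4a1 (-0.43, adjusted p = 0.00051), Ddx25 (-0.48, adjusted p = 0.000742), Btnl2 (-0.37, adjusted p = 0.000816) and Psen2 (-0.30, adjusted p = 0.00115). Of genes named for other comparisons H2-DMa was called at -0.17 per allele (adjusted p = 0.0223), in 11 of the 14 fits that left out 1 array. Slamf1 at -0.15, Hdac7 at -0.15 and Herpud1 at -0.26 passed in the trend but not in KO against WT, and each was called in 3 of those fits. With 1 array left out, 114 of the 311 genes remained called in every fit.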

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

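In this part, the tests of the dark zone list, of the fits without KO 3 and WT 4, of the slope without the chromosome of Crebbp and of its neighbouring genes were chosen after the related results were seen. An array was picked out when its gap to the nearest array of its group, divided by the range of the group, exceeded Dixon's critical value. This happened in 22 of 339 groups examined, and chance gives about 1 in 20. KO 3 was picked out 6 times and KO 5 4 times. KO 3 was lowest among KO arrays for Crebbp on its brightest probe set (gap over range 0.737, value 11.71 against 12.05 to 12.18), Map3k8 (0.835), Bid (0.821) and the apoptosis list (0.72), and highest for Slc25a24 (0.721) and Ccnb2 (0.786). KO 5 was highest for Ifnlr1 (0.807) and the glycolysis list (0.742), and lowest for Gstp3 (0.78) and for the MHC class II list (0.809). KO 2 was lowest for Dab2ip (0.731). WT 4 was highest for Ptpn9 (0.859), the unfolded protein response list (0.837) and the acetyltransferase list (0.906), and WT 3 was lowest for Ccdc175 (0.861). HET 2 was highest for Armcx4 (0.751) and Irf4 (0.798) and lowest for Bcl6 (0.714). HET 5 was lowest for Adgrl2 (0.766), HET 1 for Thyn1 (0.721), HET 3 for Herpud1 (0.764) and HET 4 for the oxidative phosphorylation list (0.98).

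Lower light zone, NF-kB and MHC class II genes in KO cells could come from genotype, handling of the cells or single arrays. A lower share of light zone cells in the sort, or strain DNA from the mixed background of the mice, could also lower them. Strain DNA was not tested for these lists, so it stays open. With the mean of the immediate early list as a covariate the KO difference of the MHC class II list was -0.22 (SE 0.04) and of the light zone list without shared genes -0.26 (SE 0.07), against -0.22 and -0.28 without the covariate. This argues against an immediate early response during handling as the whole cause. Effects of handling that these genes do not follow were not measured. Without KO 3 and WT 4 the highest camera adjusted p of the 3 lists was 4.36e-05, so the camera calls did not depend on those arrays. This holds for the preset correlation only, since camera with an estimated correlation gave adjusted p = 0.156 for each list with all arrays. A lower share of light zone cells stays open, because the dark zone list differed by 0.0222 (SE 0.04), neither clearly higher nor lower, and the sort does not part the zones.

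The place of HET cells between WT and KO may come from the allele number or from the shared WT arrays. With HET measured against 1 WT array, KO against another and genes called with the other 2, the slope averaged 0.36 and was positive in all 12 arrangements, from 0.23 to 0.45, so the shared arrays do not account for it. The changes were measured here without sex as a covariate, and the arrangements reuse 4 WT arrays. With WT 4, the only male WT mouse, used for HET the slopes were 0.234 to 0.235, against 0.35 to 0.45 for the others. Strain DNA around the floxed allele, from the mixed C57BL/6x129Sv background, would follow the allele number too, but without the genes on the chromosome of Crebbp the slope was 0.397, beside 0.403 with them. Segments of strain DNA elsewhere in the genome were not tested.

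Among the 50 tested genes nearest to Crebbp by RefSeq order on GRCm38.p6, 1 was called in KO against WT, Clec16a, which was 43rd in distance. This is 2% against 2.43% of the other 10174 genes (two-sided Fisher's exact p = 1, odds ratio 0.82, 95% interval 0.02 to 4.83). The interval is wide, so a contribution of flanking strain DNA to single genes such as Clec16a cannot be told apart from an effect of Crebbp.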

How the results depend on the processing

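Fits without KO 3 and WT 4 together or without the chromosome of Crebbp, and the split of KO arrays, were chosen after seeing the data. The genes called in KO against WT numbered 249 and those with an allele trend 311. Females alone gave 79 and 113, the loss of KO 3 and WT 4 gave 75 and 85, an adjusted p under 0.1 gave 424 and 508. Only the 2 groups compared gave 98 for KO against WT, and an unadjusted p under 0.01 with at least 1.2-fold gave 545, while array weights gave 198 for the trend. Leaving out 1 array gave 130 to 259 for KO against WT, with 144, 161, 146 and 130 without WT 1, 2, 3 and 4, and 164 to 300 for the trend, with 164 without WT 3 and 192 without WT 4. HET against WT had 0 calls, but 6 with array weights and 48 at the unadjusted threshold, and 0 whichever array was left out. KO against HET had 27 calls and was the least stable. It had 2 with no filter, 8 with a laxer filter, 9 with probe sets tested one by one, 0 in females, 72 with array weights, 5 with only the 2 groups, 13 without KO 3 and WT 4, 48 at adjusted p under 0.1 and 190 at the unadjusted threshold. Leaving out 1 array gave 0 to 25, and every array but KO 1 moved it by more than 1.5 times. Fewer arrays or more genes tested are part of several of these settings, and otherwise the cause was not tested. With an estimated correlation 0 lists were called in each comparison. Fry called 8 for KO against WT, 0 for HET against WT and 1 for KO against HET. The 8 left out the immediate early genes and held the dendritic cell markers instead. Leaving out 1 array gave 8 to 11 lists for KO against WT, 6 to 8 for KO against HET and 3 to 12 for HET against WT, with 7 without WT 1 or WT 4 and 3 without HET 5. No setting run for the lists turned the direction of a called list. The direction of named genes was checked without the sex covariate, with median centring, with the replicate block and with 1 array left out. No called named gene turned in these. Over the named genes, leaving out 1 array ended a call 354 times, made 11 and left 1455 unchanged. The HET position, a mean over arrangements of the WT arrays, was 0.376 to 0.415 over its settings. Single arrangements gave 0.390 to 0.428 with both changes measured against the same 2 WT arrays, 0.352 to 0.464 with the KO arrays split as well, and 0.234 to 0.453 with HET and KO measured against different single WT arrays. The changes behind the last range were measured without sex as a covariate. The replicate number as a block gave 198, 1, 16 and 233 genes for KO against WT, HET against WT, KO against HET and the trend, but no shared litter or batch is given for same-numbered mice in the sources used here, and the correlations did not settle a pairing. With the block 10 of the named calls of KO against WT were lost (adjusted p from 0.0541 to 0.130) and 12 of KO against HET (0.0639 to 0.125). Same-numbered arrays of different groups correlated above 0.1 in 9 of 13 pairs, with a median of 0.17 and a lowest value of -0.12, against a median of -0.05 for different numbers, and 6 of 14 arrays correlated best with one of their own number. Signal limits dim genes, since those under 6.43 were not tested.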

Other observations

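Chromatin regulators and markers of other cells held few called genes in KO against WT. Of the histone deacetylases and corepressors (camera adjusted p = 0.359) Hdac7 was at -0.30 (adjusted p = 0.0674) and passed over the list alone. The acetyltransferases and their partners had 10 positive and 12 negative changes (camera adjusted p = 0.60), and of the chromatin genes mutated in lymphoma (camera adjusted p = 0.455) Dnmt3a was at 0.43 (adjusted p = 0.105). In the NOTCH list (camera adjusted p = 0.266) Dtx1, a target of NOTCH that is also a marginal zone marker, fell by 0.41 (SE 0.10, adjusted p = 0.0496), but was called in only 2 of the 14 fits that left out 1 array.

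Camera adjusted p was 0.0512 for marginal zone markers, 0.342 for naive follicular markers, 0.488 for plasma cell markers, 0.342 for macrophage markers and 0.302 for dendritic cell markers. Of the dendritic cell markers Ly6d, which B cells also express, was at -0.47 (adjusted p = 0.144), and fry called this list lower (adjusted p = 0.0366). Markers of T cells, NK cells, neutrophils, erythroid cells and stromal cells had 4, 2, 2, 2 and 3 genes above the filter and were not tested as lists. Among them Car2, a carbonic anhydrase, rose by 0.92 (SE 0.15, adjusted p = 0.00725, called in 13 of the 14 fits) and Pecam1 fell by 0.56 (SE 0.13, adjusted p = 0.0389, called in 5), while the erythroid marker Tfrc differed by -0.05.

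Other splits of the same arrays, 100 drawn per comparison with the real one included, gave the chance level of each count. For KO against WT 1 split, the real one, reached 249 genes, with 55 the highest of the others. For the trend 1 split reached 311, with 47 the highest of the others. A share of 1 in 100, the smallest these splits allow, argues against chance for both counts, but says nothing about single genes. Both counts rest largely on the same WT and KO arrays and share 246 genes, so they are not separate evidence. For KO against HET 4 splits reached 27 genes and the highest of the others had 552, which points to a structure of the samples. The split with 552 genes set HET 4, HET 5, KO 2, KO 4 and KO 5, the HET and KO arrays with the highest values on the first principal component, against the other 5. For HET against WT all 100 splits reached 0, and the highest of the others had 14. For lists, 21 splits gave the 8 of KO against WT, with 13 the highest of the others, and 22 gave the 7 of KO against HET, with 12 the highest, so chance cannot be excluded for these counts. The median of the other splits was 3 lists in each of these comparisons. For HET against WT 3 splits gave 11 lists, with 12 the highest of the others.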
